A study of Homo sapiens with 12 samples.

How the data were processed

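Splicing was measured by RNA sequencing in MCF7 cells. Per the labels, the 12 libraries were strand-specific libraries of total RNA depleted of ribosomal RNA, made 48 hours after transfection with siRNA at 30 nM. Per the submitters' processing notes, cutadapt 1.13, TopHat2 2.0.13 and SAMtools 0.1.19 were used with build hg19. The program that called the splicing events and its annotation were not given in the sources used here. Samples were grouped from the labels and file names: 3 libraries depleted of DDX5 and DDX17 against 3 siGL2 libraries, and 1 library each for 5 other depletions against 1 further siGL2 library. The labels describe the siGL2 libraries as treated with a negative control siRNA.

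The authors deposited a PSI for each event and library as a fraction from 0 to 1, with no library scaling. The deposited difference of PSI is a score, depleted minus control, taken between the medians of 3 libraries or between single libraries. Each p-value in the deposited tables is from the authors' own model (a generalized linear model for the triplicates, a Fisher test for single libraries), given raw and corrected by a method that was not stated. The other deposited columns used are counts of events, per the file headers, and a length for alternative splice sites, whose meaning is not given and which is read here as nucleotides. Per the file headers, the authors' thresholds were a PSI difference of 0.10 and a corrected p of 0.05, in an unpaired analysis. The tables list only events past these thresholds. The authors' deposited totals for skipped exons were 2553 of 25433 (10.0%) after DDX5 and DDX17, 521 of 20197 (2.58%) after FUS, 631 of 20906 (3.02%) after HNRNPC, 338 of 20835 (1.62%) after HNRNPH1, 556 of 20845 (2.67%) after HNRNPK, and 2604 of 23215 (11.2%) after TRA2A and TRA2B depletion. The tables used here hold no read counts, so neither the depth per library nor the precision of a single PSI could be given.

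The planned tests on read counts were replaced, because the tables hold fractions only. For DDX5 and DDX17, PSI with 0.01 added to the included and the skipped fraction was put on the logit scale and tested in limma 3.58.1 under R 4.3.3, each event type in its own fit, with Benjamini-Hochberg adjustment over the tested events of that type. Events with a PSI in all 6 libraries were tested, 2244 of 2553 skipped exons. An event counted as changed at an adjusted p under 0.05 and a difference of mean PSI of at least 0.10. These adjusted p-values cover events that the authors had already selected on the same libraries, so they are too small as a rate over all events. The test was run on simulated data of 2244 events with 50 per shift: it recovered 62%, 52%, 6% and 4% of shifts of -6, -4, -2 and 2 in log2 odds, with 0 of the wrong sign, and called 7 of 2044 unchanged events. For single libraries the authors' calls were used as listed, with no test of conditions.

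Shares were given exact binomial intervals. Exon lengths were compared by medians, a bootstrap interval and percentiles among 10000 random lists of the same size from the same table; the lists could not be matched on reads, and GC content, which needs the genome sequence, was not analysed here. Exons were matched between comparisons by gene, exact coordinates and exon number, so an exon listed under several genes counts once for each. Overlaps were set against independent lists among all events of the smaller of the 2 totals, and, for single libraries, against a simulation of unchanged libraries sharing 1 control. The simulation gave each library equal normal noise, used the largest raw p listed in each table as its threshold, and left out any departure of the shared control beyond that noise. Counting, intervals and random lists used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. Of 5174 gene symbols in the tables, 4435 were current in the RefSeq names of GRCh38.p14, 645 were older symbols with 1 current name, and 94 were unmatched or matched several. That table served for names only.

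The 14 gene lists, the comparisons and the rule for naming exons were fixed before the data were examined. The rule took, among changed exons, the 8 largest rises and falls after DDX5 and DDX17 depletion, the 6 largest of each in the other comparisons, up to 4 changed members per list, 2 events per direction of the other types, events of the 8 targeted genes, and exons changed in 4 or more comparisons. Its minimum of reads could not be applied. For DDX5 and DDX17, the largest changes and the list members had to have all 3 libraries of 1 group beyond all 3 of the other. The separation of libraries in these events is therefore a rule of selection, not a result. Each of these selections took 1 event per gene. Printed examples are drawn from the events so named, first those past the thresholds under each alternative run. Gene lists were set against random lists of the same size drawn from the genes of all tables. These genes were each listed in some comparison and were not matched on their number of exons. The random values thus set a list against the other comparisons, not against all genes. Alternatives tried were the replicate number as a block, leaving out each library, other PSI differences, a corrected p of 0.01, other amounts added to PSI, untransformed PSI, a quasibinomial model, missing values kept, the authors' p-values, 1 event per set of coordinates, a mid-range of control PSI, other exon selections and other matching rules.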

Results

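Alternative splicing was compared in MCF7 cells, a breast cancer line, after siRNA depletion of splicing factors and other RNA-binding proteins. The 12 libraries were strand-specific libraries of total RNA freed of ribosomal RNA, from cells collected 48 hours after transfection with siRNA at 30 nM. They formed 2 experiments. In the first, DDX5 and DDX17 were depleted together in 3 libraries and compared with 3 libraries of the control siRNA siGL2. The series record describes these triplicates as coming from different batches of cells, and no other batch or date is given. In the second, 1 library each was made after depletion of FUS, HNRNPC, HNRNPH1, HNRNPK, or TRA2A and TRA2B together, and all 5 were compared with 1 further siGL2 library, so these comparisons had no replicates. Each comparison asked which exons change their inclusion when the factor is lost. The measured value was the inclusion level of an exon in a library (percent spliced in, PSI, given here as a fraction from 0 to 1), for skipped exons, runs of several skipped exons, alternative acceptor sites, alternative donor sites and mutually exclusive exons. The tables used here hold no read counts, so the depth behind each PSI is unknown and no interval is given for a single PSI. The deposited tables listed only events past the authors' thresholds, a PSI difference of at least 0.10 and a corrected p of at most 0.05. In the single-library comparisons, "changed", "rose" and "fell" refer to the events listed by the authors, whose Fisher test compares 2 libraries, not 2 conditions. In the replicated comparison these words refer to events past a limma test on the 3 libraries of each group, whose p-values measure the spread between libraries. Coordinates are those of build hg19.

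Gene expression was not analysed here, so the loss of the 8 targeted genes themselves could not be checked. Several of them had listed events in their own transcripts or in those of each other. For a gene in its own depletion, the value comes from the transcripts left after the siRNA, without replicates. It need not reflect splicing itself. A run of exons 2 and 3 of HNRNPC rose from 0.516 in the siGL2 library to 0.895 after HNRNPC depletion. The same run fell to 0.291 after FUS depletion and to 0.402 after HNRNPH1 depletion. After DDX5 and DDX17 depletion it fell from 0.471 ± 0.048 to 0.192 ± 0.013 (SD, n = 3; limma adjusted p = 0.025), a call lost when control replicate 1, 2 or 3 was left out (PSI differences of -0.251, -0.294 and -0.292). Inclusion of a run of exons 2, 3 and 4 of TRA2B fell from 0.897 to 0.509 after TRA2A and TRA2B depletion, to 0.753 after HNRNPC depletion and to 0.786 after FUS depletion. In the replicated comparison this run was at 0.772 ± 0.10 against 0.927 ± 0.0035 in the controls and did not pass (limma adjusted p = 0.062, n = 3). A run of exons 2 and 3 of TRA2A, at 0.278 ± 0.15 against 0.0556 ± 0.048, did not pass either (limma adjusted p = 0.073, n = 3). In HNRNPK, use of one donor site of exon 2 fell from 0.689 to 0.467 after depletion of HNRNPK itself and to 0.511 after HNRNPH1 depletion. Use of an acceptor site of its exon 18 rose from 0.392 to 0.766 after HNRNPC depletion and to 0.508 after HNRNPH1 depletion. After TRA2A and TRA2B depletion, inclusion fell for exon 9 of HNRNPC (0.997 to 0.560), exon 13 of HNRNPH1 (0.903 to 0.667), exon 13 of DDX5 (0.992 to 0.808) and exon 5 of TRA2A (1 to 0.875). No event of FUS or DDX17 was listed in any table.

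Loss of DDX5 and DDX17, a pair of closely related DEAD-box RNA helicases, mostly lowered exon inclusion. Of 2244 skipped exons tested, 1382 changed in 1206 genes, 1248 of them lower and 134 higher, so 90.3% fell (exact 95% interval 88.6 to 91.8, for the counting of exons only). Here and below an exon listed under several genes counts once for each, and the 1382 are 1360 sets of coordinates. Exon 6 of TBX2, a T-box transcription factor (chromosome 17, 59482563 to 59483197), fell from 0.993 ± 0.0086 to 0.116 ± 0.033 (SD, n = 3; limma adjusted p = 0.0012). Exon 3 of the zinc finger gene ZKSCAN4 (chromosome 6, 28215845 to 28215927) fell from 1 in each control library to 0.166 ± 0.040 (limma adjusted p = 0.0012). Exon 8 of C18orf1, now named LDLRAD4 (chromosome 18, 13643358 to 13643411), fell from 0.95 ± 0.056 to 0.0998 ± 0.11 (limma adjusted p = 0.0043). Exon 8 of CEP72, which encodes a centrosomal protein (chromosome 5, 639204 to 639339), fell from 1 to 0.201 ± 0.20 (limma adjusted p = 0.0029). An exon at chromosome 8, 144356046 to 144357179, listed under both GLI4 and ZFP41, fell from 1 to 0.148 ± 0.26, and one at chromosome 2, 220081374 to 220081554, listed under both ABCB6 and ATG9A, fell from 0.969 ± 0.040 to 0.170 ± 0.17. Which gene of each pair the change belongs to cannot be said from the tables.

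Fewer exons rose. Exon 2 of KLHL20, which encodes a substrate adaptor of a ubiquitin ligase (chromosome 1, 173684704 to 173684793), rose from 0.257 ± 0.092 to 0.910 ± 0.042 (SD, n = 3; limma adjusted p = 0.0018). Exon 8 of the inositol hexakisphosphate kinase gene IP6K2 (chromosome 3, 48752748 to 48752960) rose from 0.0760 ± 0.049 to 0.559 ± 0.033 (limma adjusted p = 0.0029). Exon 2 of CHCHD4, an import factor of the mitochondrial intermembrane space (chromosome 3, 14163417 to 14163586), rose from 0.0495 ± 0.035 to 0.523 ± 0.12 (limma adjusted p = 0.0031). The other 5 of the 8 largest rises each lost their call without some library. PPP1R13B exon 6, at 0.715 ± 0.25 against 0.0459 ± 0.050, lost it without control replicate 2 (difference 0.646). BAZ2B exon 20, at 0.958 ± 0.073 against 0.482 ± 0.25, lost it without depleted replicate 2 (0.454). C7orf42 exon 2 (now TMEM248), at 0.537 ± 0.29 against 0.0653 ± 0.059, lost it without depleted replicate 1 (0.450), control replicate 2 (0.449) or control replicate 3 (0.462). C8orf38 exon 13 (now NDUFAF6), at 0.530 ± 0.42 against 0.00725 ± 0.013, lost it without control replicate 1, 2 or 3 (0.519, 0.519 and 0.530). METTL6 exon 6, at 0.637 ± 0.18 against 0.145 ± 0.13, lost it without depleted replicate 1, 2 or 3 (0.397, 0.505 and 0.575) or control replicate 2 or 3 (0.420 and 0.520).

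**Figure D1:**
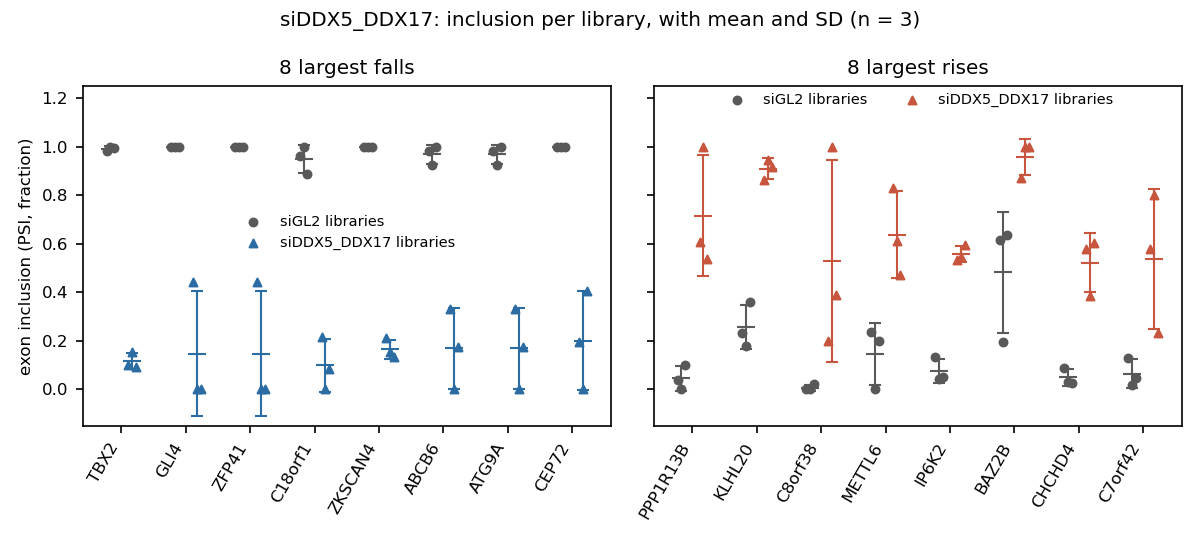
Inclusion (PSI, a fraction) of the 8 listed skipped exons with the largest falls and the 8 with the largest rises after DDX5 and DDX17 depletion (the exons of GLI4 and ZFP41, and of ABCB6 and ATG9A, are the same and are shown under each gene), with 1 point per library, the mean as a horizontal line and the SD as error bars (n = 3 depleted and 3 siGL2 libraries). TBX2 lies at 0.116 against 0.993 and KLHL20 at 0.910 against 0.257. Bars reach beyond 0 or 1 where the SD does. Only exons with all 3 libraries of 1 group beyond all 3 of the other were eligible.

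Among gene lists fixed beforehand, the list of other splicing regulators and RNA-binding proteins held 29 changed exons among 42 tested (24 lower and 5 higher; 29 adjusted over the list alone), in 26 of its 57 genes present in any table, against 17.6 genes in random lists of this size. In it, exon 7 of CPSF7, a 3' end processing factor, fell from 0.985 ± 0.025 to 0.455 ± 0.024, exon 20 of ILF3 from 0.970 ± 0.027 to 0.528 ± 0.13, and exon 47 of SMG1, a kinase of nonsense-mediated decay, from 1 to 0.603 ± 0.20 (SD, n = 3). The hnRNP and poly(C) or polypyrimidine binding proteins had 7 changed exons among 10 tested (5 lower and 2 higher; 9 adjusted over the list alone; 7 genes against 5.87 in random lists), among them HNRNPUL2 exon 12 (0.873 ± 0.017 to 0.335 ± 0.085) and HNRNPR exon 6 (0.946 ± 0.0084 to 0.712 ± 0.026). The SR proteins had 2 of 3 (1 in each direction; 3 adjusted over the list alone; 2 genes against 1.85), with SFRS11 exon 2 falling from 1 to 0.760 ± 0.13. The list for U2 snRNP and 3' splice site recognition had 4 of 7, all lower (4 adjusted over the list alone; 3 genes against 4.64), with SF3A2 exon 2 falling from 1 to 0.748 ± 0.15. The list for U1 snRNP and 5' splice site recognition had 1 exon tested, which did not pass in limma, alone or among all exons, against 3.06 genes with a changed exon in random lists.

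Chromatin regulators and histone variants had 40 changed exons among 63 tested (33 lower and 7 higher; 40 adjusted over the list alone; 32 genes against 31.9 in random lists). Exon 8 of the deacetylase gene HDAC11 fell from 0.984 ± 0.028 to 0.320 ± 0.28, exon 39 of the remodeller CHD3 from 0.932 ± 0.072 to 0.279 ± 0.088, exon 20 of the DNA methyltransferase DNMT3A from 1 to 0.355 ± 0.36, and exon 12 of the histone methyltransferase EHMT1 from 0.947 ± 0.067 to 0.323 ± 0.079 (SD, n = 3). DNA repair and checkpoint genes had 11 of 25 (8 lower, 3 higher, and 9 adjusted over the list alone). They covered 11 genes against 18.5 in random lists (percentile 1.5). Random lists came from genes listed in any comparison, and 41 of the 60 repair genes there were listed after TRA2A and TRA2B depletion. The 18.5 thus depends on the other depletions and is not a value for all genes. In this list, exon 9 of the checkpoint kinase CHEK1 fell from 0.994 ± 0.011 to 0.507 ± 0.10 and exon 13 of FANCA from 1 to 0.607 ± 0.11, while exon 8 of the mismatch repair gene MLH3 rose from 0.605 ± 0.19 to 0.965 ± 0.039. The list of cell division, spindle and centrosome genes had 27 of 40 (24 lower and 3 higher; 27 adjusted over the list alone; 25 genes against 25.3), with CDK2 exon 5 falling from 0.955 ± 0.042 to 0.439 ± 0.14. Apoptosis genes had 8 of 14 (7 lower and 1 higher; 8 adjusted over the list alone; 8 genes against 5.89), with falls in BCL2L12 exon 6 (0.968 ± 0.023 to 0.172 ± 0.076), API5 exon 8 (0.979 ± 0.0032 to 0.258 ± 0.041) and exon 4 of the death agonist BID (0.975 ± 0.026 to 0.430 ± 0.13).

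Genes of the cytoskeleton, adhesion and polarity had 41 changed exons among 63 tested (38 lower and 3 higher; 42 adjusted over the list alone; 30 genes against 22 in random lists). Exon 11 of EPB41L1 fell from 1 to 0.325 ± 0.26, exon 42 of the laminin chain LAMA5 from 1 to 0.506 ± 0.091, and exon 17 of DLG5 from 0.956 ± 0.077 to 0.481 ± 0.18 (SD, n = 3). Membrane traffic genes had 27 of 54 (26 lower and 1 higher; 26 adjusted over the list alone; 22 genes against 25.0), including exon 4 of the syntaxin STX16 (0.664 ± 0.10 to 0.110 ± 0.016) and exon 19 of the sorting nexin SNX14 (0.509 ± 0.13 to 0.0766 ± 0.064). Estrogen response and nuclear receptor genes had 11 of 18 (10 lower and 1 higher; 12 adjusted over the list alone; 6 genes against 6.5), including exon 6 of the cell cycle transcription factor FOXM1 (0.813 ± 0.12 to 0.103 ± 0.11) and exon 12 of the corepressor NCOR2 (0.990 ± 0.017 to 0.641 ± 0.044). Of published splicing targets of the depleted factors, 8 of 14 tested exons changed (6 lower and 2 higher; 10 adjusted over the list alone; 6 genes against 5.24), with exon 8 of TARBP2 falling from 0.849 ± 0.012 to 0.338 ± 0.10 and exon 12 of the tau gene MAPT rising from 0.237 ± 0.13 to 0.694 ± 0.081. The list of published targets pools those of all the depleted factors, so it gives no rate for DDX5 and DDX17 alone. None of the 25 markers of immune, stromal, endothelial, muscle and neural cells was listed in any of the 6 comparisons.

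Runs of several exons moved the same way as single exons. Of 1228 listed runs, 525 changed after DDX5 and DDX17 depletion, 489 lower and 36 higher (93.1% lower, exact 95% interval 90.6 to 95.2). A run of exons 11 and 12 of the endocytic adaptor EPN2 fell from 1 to 0.0470 ± 0.046 (SD, n = 3; limma adjusted p = 0.00095), and a run of exons 16 and 17 of C6orf70 (now ERMARD) from 1 to 0.105 ± 0.12 (limma adjusted p = 0.0015). A switch between the mutually exclusive exons 7 and 8 of H2AFY, which encodes the histone variant macroH2A1, took the listed form from 0.0928 ± 0.018 to 0.545 ± 0.0022 (limma adjusted p = 0.0012). It was 1 of 5 changed pairs of mutually exclusive exons. Acceptor sites changed in 72 exons and donor sites in 120. Exon 6 of PTK6, a breast tumour kinase, changed at both ends, with the listed acceptor falling from 1 to 0.129 ± 0.10 and the listed donor from 0.916 ± 0.13 to 0.0443 ± 0.027 (limma adjusted p = 0.00082 and 0.0036). The listed acceptor of CAMTA1 exon 17 fell from 0.883 ± 0.13 to 0.0476 ± 0.082, and the listed donor of KREMEN1 exon 7 from 0.895 ± 0.091 to 0.0440 ± 0.076.

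The replicated test was run on the 2244 of 2553 listed skipped exons that had a PSI in all 6 libraries, and the authors' deposited table held all 2553 as changed (2284 lower and 269 higher). The median PSI of the listed exons was 0.732, 0.721 and 0.745 in the depleted libraries and 0.992, 1 and 1 in the controls. A PSI was missing for 45, 159 and 77 of the 2553 exons in the depleted libraries and for 6, 19 and 21 in the controls. Of the changed exons, 1044 had a control PSI above 0.9, from which a rise of 0.10 is not possible. Among the 89 with a control PSI of 0.3 to 0.7, 68 fell and 21 rose (76.4% lower, exact 95% interval 66.2 to 84.8).

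Depletion of FUS, an RNA-binding protein of the FET family, changed 521 skipped exons in 497 genes, 329 lower and 192 higher. Exon 25 of CENPE, a kinetochore motor protein (chromosome 4, 104074204 to 104074407), fell from 0.788 to 0.0909. Exon 5 of FAM63A, now MINDY1 (chromosome 1, 150974641 to 150975444), fell from 0.881 to 0.312, and exon 19 of CASK, a scaffold kinase (chromosome X, 41416285 to 41416353), from 0.654 to 0.103. A listed run of exons 19 and 20 of CASK rose instead (PSI difference of 0.576). Events that hold CASK exon 19 thus went in opposite directions in this library. An exon listed under both HDAC10 and MAPK12 (chromosome 22, 50686121 to 50686205) fell from 1 to 0.419. Exon 10 of ARHGAP11B fell from 0.644 to 0.10, but this gene has a near-identical partner, so its value is uncertain. Rises included exon 2 of C6orf52 (chromosome 6, 10687713 to 10687794; 0.0714 to 0.694), exon 13 of the corepressor RCOR3 (0.138 to 0.727), exon 3 of the exonuclease EXO1 (0.370 to 0.897), exon 2 of KLHL20 (0.203 to 0.712), exon 9 of NDEL1 (0.340 to 0.826) and exon 2 of CDKAL1 (0.0635 to 0.544). In the list for U1 snRNP and 5' splice site recognition, 4 of 10 genes present in any table had a changed exon, all higher: PRPF39 exon 4 (0.252 to 0.643), RBM25 exon 12 (0.183 to 0.490), LUC7L exon 5 (0.0848 to 0.303) and SNRNP70 exon 8 (0.0838 to 0.270). Random lists of this size drawn from the genes of all tables held 1.30 such genes on average. Against the same siGL2 library, LUC7L exon 5 also rose after HNRNPH1 and HNRNPK depletion (PSI differences of 0.220 and 0.178). The hnRNP list had 6 genes of 19 (2.42 in random lists), with HNRNPD exon 7 rising (0.445 to 0.698) and HNRNPUL1 exon 17 falling (0.952 to 0.711). Other RNA-binding proteins had 13 genes of 57 (7.27), with rises in UPF3A exon 4 (0.447 to 0.842) and UPF3B exon 8 (0.263 to 0.629), a pair of nonsense-mediated decay factors. The UPF3B exon also rose after HNRNPC depletion (PSI difference of 0.384). Chromatin regulators had 15 genes of 103 (13.1), with BPTF exon 6 rising from 0.323 to 0.644. The cell division list had 14 of 82 (10.5), the cytoskeleton list 15 of 71 (9.11), the DNA repair list 9 of 60 (7.63) and the membrane traffic list 13 of 81 (10.3). The remaining lists had 2 genes for SR proteins (0.760), 3 for U2 (1.91), 3 for estrogen response (2.67), 3 for published targets (2.17) and 1 for apoptosis (2.43).

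Depletion of HNRNPC, which binds uridine tracts in nascent transcripts, changed 631 skipped exons in 587 genes, 368 lower and 263 higher. Exon 2 of the replication factor GINS3 (chromosome 16, 58429006 to 58429122) rose from 0.0750 to 0.909, and exon 5 of COPS7B, a subunit of the COP9 signalosome (chromosome 2, 232654364 to 232655883), from 0.0417 to 0.750. Exon 2 of SPOP, a ubiquitin ligase adaptor, rose from 0.261 to 0.952, exon 2 of UBE2CBP (now UBE3D) from 0.10 to 0.795, exon 16 of ADAM2 from 0.231 to 0.898, and exon 3 of the uracil DNA glycosylase SMUG1 from 0.292 to 0.935. Falls included exon 9 of GUF1 (chromosome 4, 44690024 to 44690163; 0.767 to 0.148), exon 16 of the adaptor GRB7 (0.826 to 0.208), exon 49 of the telomerase component TEP1 (0.875 to 0.273), exon 9 of the kinase SYK (0.817 to 0.284), exon 2 of AP3M2 (0.516 to 0) and exon 2 of ARRB2 (0.759 to 0.255). In the list of DNA repair and checkpoint genes, 23 of 60 genes present in any table had a changed exon, with 19 exons lower and 9 higher. Random lists of this size held 9.03 such genes on average, and this list lay at percentile 100 of 10000 random lists. Exon 34 of the kinase ATM fell from 1 to 0.682, exon 12 of BRCA2 from 0.897 to 0.609, exon 2 of XRCC3 from 0.784 to 0.473 and exon 5 of MLH3 from 0.651 to 0.321. Their corrected p in the authors' Fisher test was 0.017, 0.048, 0.011 and 0.018, each above 0.01. Against the same siGL2 library, the XRCC3 exon also fell after HNRNPH1 depletion (PSI difference of -0.295). With a PSI difference of at least 0.20, 9 exons of the list remained. Chromatin regulators had 17 genes of 103 (15.5 in random lists), including rises in ASXL1 exon 11 (0.521 to 1), KDM5B exon 7 (0.149 to 0.551) and SMARCA4 exon 30 (0.0411 to 0.409). Membrane traffic genes had 20 of 81 (12.2), including GGA3 exon 3 (0.296 to 0.848) and NUMB exon 11 (0.865 to 0.444). Other RNA-binding proteins had 12 of 57 (8.56), including STAU1 exon 3 (0.222 to 0.583) and FXR1 exon 18 (0.449 to 0.726). The cell division list had 14 of 82 (12.3), with CENPK exon 3 falling from 0.678 to 0.277 and CENPL exon 5 rising from 0.162 to 0.559. The remaining lists had 15 genes for the cytoskeleton (10.7), 4 for published targets (2.54), 3 for apoptosis (2.83), 3 for estrogen response (3.13), 2 for hnRNPs (2.85), 2 for U2 (2.29), 1 for U1 (1.52) and 0 for SR proteins (0.899).

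Depletion of HNRNPH1, which binds runs of G, changed 338 skipped exons in 329 genes, 204 lower and 134 higher. Exon 17 of the proprotein convertase PCSK6 (chromosome 15, 101871856 to 101871894) fell from 0.645 to 0.120, and exon 3 of MORN1 (chromosome 1, 2321364 to 2321435) from 0.906 to 0.385. Other falls were in HMGXB4 exon 2 (0.795 to 0.278), NEURL4 exon 3 (0.846 to 0.353), LRRC23 exon 7 (0.750 to 0.30) and KREMEN2 exon 8 (0.689 to 0.240). Exon 13 of KIAA1217 (chromosome 10, 24783429 to 24783533) rose from 0.0385 to 0.714, exon 11 of IP6K2 from 0.125 to 0.641, exon 8 of WASF3, an actin regulator, from 0.0645 to 0.526, exon 6 of the interferon regulatory factor IRF7 from 0.419 to 0.879, and exon 18 of the ubiquitin ligase NEDD4L from 0.30 to 0.750. Exon 21 of HERC2P9, a pseudogene copy, was at 0.640 against 0.111 and is uncertain. Exon 7 of MYL6, a myosin light chain, rose from 0.378 to 0.605, one of 11 changed exons in the cytoskeleton list (11 genes against 5.96 in random lists). Exon 11 of the translation factor EIF4A2 fell from 0.334 to 0.135, and exon 8 of HNRPDL (now HNRNPDL) rose from 0.113 to 0.244. The cell division list had 11 genes of 82 (6.92), with CENPE exon 17 (0.815 to 0.50) and ESPL1 exon 6 (1 to 0.750) falling. The DNA repair list had 7 of 60 (5.05), with XRCC3 exon 2 falling from 0.784 to 0.489 and exon 8 of ATRIP, a checkpoint partner of ATR, rising from 0.744 to 0.978. Chromatin regulators had 9 of 103 (8.72) and membrane traffic genes 9 of 81 (6.85), including exon 14 of the endocytic adaptor PICALM (0.474 to 0.277). The remaining lists had 4 genes for other RNA-binding proteins (4.79), 3 for estrogen response (1.78), 2 for apoptosis (1.63), 2 for published targets (1.43), 1 for hnRNPs (1.61), 1 for U1 (0.828), 1 for U2 (1.27) and 0 for SR proteins (0.496). Beyond skipped exons, alternative donor sites changed in 165 exons after HNRNPH1 depletion and acceptor sites in 85.

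Depletion of HNRNPK, which binds C-rich sequences, changed 556 skipped exons in 536 genes, 313 lower and 243 higher. Exon 15 of SMARCD3, a subunit of the SWI/SNF remodeller (chromosome 7, 150936482 to 150936583), fell from 0.922 to 0.294. Exon 12 of the splicing repressor PTBP2 (chromosome 1, 97271975 to 97272008) fell from 0.676 to 0.123, exon 2 of ARRB2 from 0.759 to 0.185, exon 5 of FAM107B from 0.760 to 0.214 and exon 2 of IQCE from 0.944 to 0.408. Exon 4 of C11orf95, now ZFTA (chromosome 11, 63531510 to 63532070), rose from 0.30 to 1, exon 6 of IRF7 from 0.419 to 1, exon 5 of DNAJC27 from 0.0952 to 0.696, exon 2 of TMEM188 (now CNEP1R1) from 0.0357 to 0.595 and exon 3 of FBXO44 from 0.214 to 0.767. Exons of WASH6P (0.304 to 0.95) and HIATL2 (0.879 to 0.370) belong to copies with near-identical relatives and are uncertain. Chromatin regulators had 22 genes of 103 with a changed exon against 14.2 in random lists, including rises in SETMAR exon 2 (0.106 to 0.582) and exon 11 of the methyltransferase EHMT2 (0.561 to 0.917). The hnRNP list had 4 genes of 19 (2.61), with HNRPDL exon 8 rising from 0.113 to 0.401 and PCBP2 exon 15 falling from 0.740 to 0.558. The U2 list had 4 of 15 (2.07), with RBM5 exon 6 falling from 0.949 to 0.794. The DNA repair list had 10 of 60 (8.23), including exon 3 of FANCI (0.222 to 0.739) and exon 2 of MDM2, the ligase of p53 (0.323 to 0.526). The cytoskeleton list had 16 of 71 (9.75), including CLASP1 exon 30 (0.253 to 0.663) and exon 24 of the tight junction gene TJP1 (0.162 to 0.391). The estrogen response list had 6 of 21 (2.90), including a fall in exon 5 of the thyroid receptor THRB (0.600 to 0.171). The remaining lists had 14 genes for cell division (11.2), 10 for membrane traffic (11.1), 6 for other RNA-binding proteins (7.81), 3 for U1 (1.39), 2 for apoptosis (2.59), 2 for published targets (2.35) and 0 for SR proteins (0.823). Acceptor sites changed in 153 exons, with the listed acceptor of exon 48 of the citron kinase gene CIT falling from 0.955 to 0.0909.

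Depletion of TRA2A and TRA2B, SR-like activators that bind purine-rich exonic sequences, changed 2604 skipped exons in 2037 genes, 2174 lower and 430 higher. Some exons went from full inclusion to none: exon 22 of OFD1, a centriolar protein gene (chromosome X, 13785246 to 13785403), and exon 7 of FAM65C, now RIPOR3 (chromosome 20, 49227390 to 49227443), both fell from 1 to 0. Exon 12 of C14orf106 (now MIS18BP1), a gene of centromere assembly, fell from 1 to 0.0588, exon 8 of CASD1 to 0.0606, exon 24 of the ciliary gene CEP290 to 0.0833 and exon 5 of TXNDC16 to 0.0909. Rises included exon 3 of the tRNA synthetase FARSB (chromosome 2, 223511520 to 223511715; 0.168 to 0.976), exon 4 of DICER1, the nuclease of microRNA maturation (0.167 to 0.926), exon 3 of PI4KB (0.256 to 0.905), exon 11 of IP6K2 (0.125 to 0.737) and exon 3 of MZF1 (0.118 to 0.704). Exon 2 of ZNF252, a pseudogene copy, was at 0.672 against 0.0964 and is uncertain. In the list of cell division, spindle and centrosome genes, 55 of 82 genes present in any table had a changed exon against 42.8 in random lists, with 75 exons lower and 7 higher. They included CEP164 exon 22 (1 to 0.118), CEP70 exon 15 (0.892 to 0.111) and CEP57 exon 8 (0.838 to 0.0588). DNA repair and checkpoint genes had 41 of 60 against 31.3 in random lists, with 57 exons lower and 7 higher. They included falls in exon 8 of RAD18 (0.982 to 0.154), exon 13 of the mismatch repair gene PMS1 (0.953 to 0.143), exon 6 of RNF8 (0.800 to 0.0435) and exon 10 of UIMC1 (1 to 0.342). Chromatin regulators had 56 of 103 against 53.8, with falls in exon 3 of the DNA glycosylase MBD4 (0.990 to 0.228), exon 20 of MLL5 (now KMT2E; 1 to 0.269) and exon 5 of TET2 (0.987 to 0.462).

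The same depletion changed splicing regulators themselves. Exon 10 of SRPK1, a kinase of SR proteins, fell from 0.997 to 0.164, exon 20 of SMG1 from 0.971 to 0.339, exon 4 of U2AF1, a subunit of the 3' splice site factor, from 0.622 to 0.240, and exon 12 of HNRNPM from 0.756 to 0.470. Exon 7 of PUF60 rose from 0.510 to 0.755. Of 6 SR protein genes present in any table, 4 had a changed exon (3.10 in random lists), with SFRS6 exon 3 (0.0378 to 0.223), SRSF2 exon 3 (0.0664 to 0.225) and SFRS7 exon 4 (0.0246 to 0.130) rising. Apoptosis genes had 13 of 19 (9.94), with exon 3 of the caspase inhibitor XIAP falling from 0.741 to 0.0423 and exon 6 of CFLAR rising from 0.10 to 0.577. Membrane traffic genes had 43 of 81 (42.3), with exon 57 of VPS13A falling from 0.989 to 0.222, and cytoskeleton genes had 36 of 71 (37.1), with exon 47 of DST falling from 0.988 to 0.260. Estrogen response genes had 12 of 21 (10.9), with exon 5 of the transcription factor MYB falling from 0.986 to 0.364. Among published targets, 11 of 17 genes had a changed exon (8.89 in random lists), including CHEK1 exon 4 (0.562 to 0.0862), GLYR1 exon 6 (0.952 to 0.347) and KIF14 exon 11 (1 to 0.421). This list pools targets of all the depleted factors, so it gives no rate for TRA2A and TRA2B alone. Against the same siGL2 library, KIF14 exon 11 also fell after HNRNPC and FUS depletion (PSI differences of -0.308 and -0.167). CHEK1 exon 4 rose after HNRNPC depletion (0.188). The remaining lists had 36 genes for other RNA-binding proteins (29.7), 13 for hnRNPs (9.91), 8 for U2 (7.82) and 7 for U1 (5.23). A run of exons 2 and 3 of CSDE1 fell from 0.972 to 0.0351 and a run of exons 3 to 6 of the excision repair gene XPA from 1 to 0.0787. A run in SULT1A4 was at 1 against 0.219, but this gene has a near-identical copy and its value is uncertain.

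**Figure D2:**
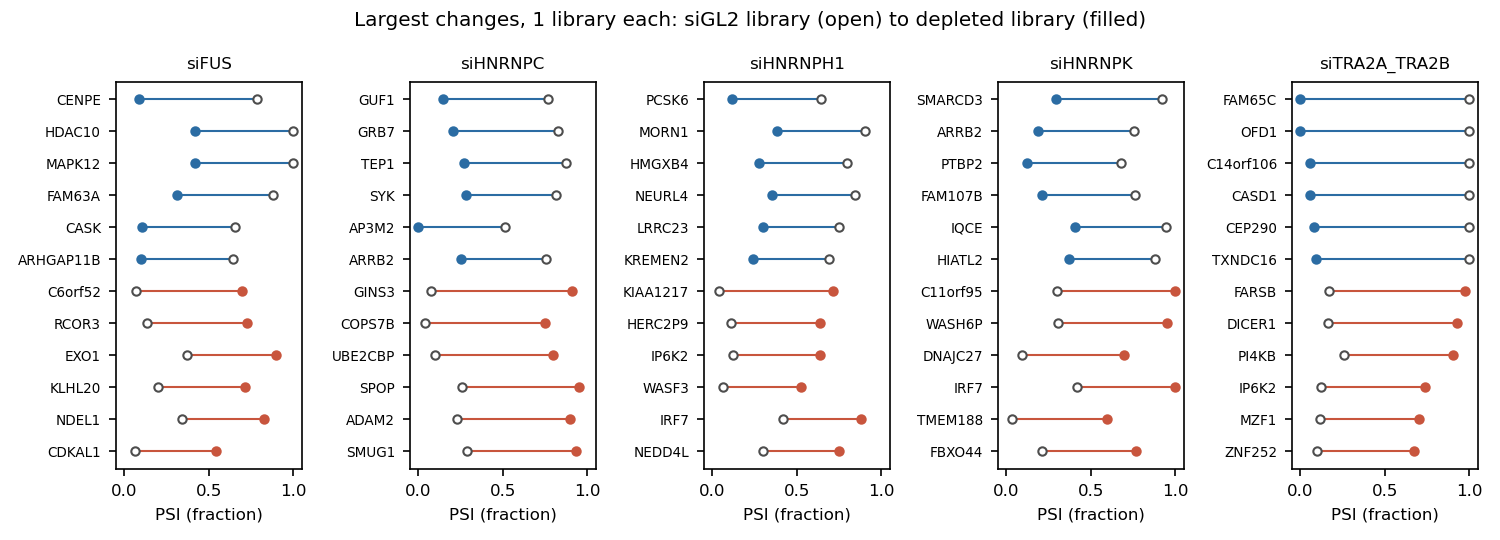
Inclusion (PSI, a fraction) of the 6 listed skipped exons with the largest falls (blue) and the 6 with the largest rises (red) in each single-library comparison (for FUS, HDAC10 and MAPK12 share 1 exon, shown under both), from the siGL2 library (open circles) to the depleted library (filled circles), with 1 library each and no replicates. CENPE after FUS depletion goes from 0.788 to 0.0909, and OFD1 after TRA2A and TRA2B depletion from 1 to 0.

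The balance of lower and higher inclusion differed between the depletions. After TRA2A and TRA2B depletion 83.5% of changed skipped exons were lower (exact 95% interval 82.0 to 84.9), against 63.1% after FUS (58.8 to 67.3), 60.4% after HNRNPH1 (54.9 to 65.6), 58.3% after HNRNPC (54.4 to 62.2) and 56.3% after HNRNPK depletion (52.1 to 60.5). The intervals cover the counting of exons in these libraries only. Among exons with a control PSI of 0.3 to 0.7, the share was 57.0% after TRA2A and TRA2B (50.8 to 63.0), 50% after HNRNPC (41.6 to 58.4), 45.2% after FUS (35.9 to 54.8), 43.8% after HNRNPH1 (32.2 to 55.9) and 40.8% after HNRNPK depletion (32.1 to 49.9). The share thus crossed 50% for the last 3 factors, with intervals that included 50% for FUS and HNRNPH1. Runs of several exons were lower in 88.3% of cases after TRA2A and TRA2B, 73.2% after HNRNPH1, 72.8% after FUS, 70.7% after HNRNPK and 49.4% after HNRNPC depletion.

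**Figure D3:**
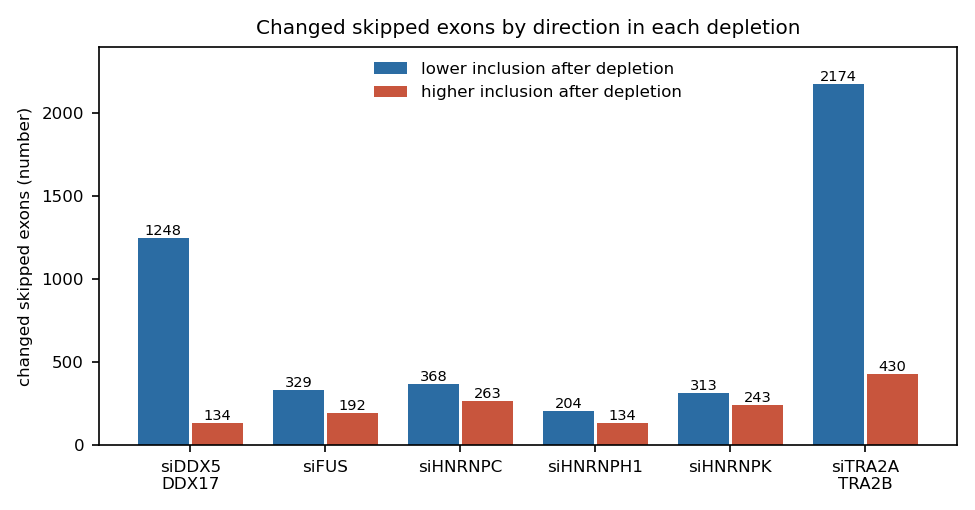
Number of changed skipped exons with lower (blue) and higher (red) inclusion after each depletion, from limma for DDX5 and DDX17 (3 libraries per group) and from the authors' deposited tables for the others (1 library per group). Falls outnumber rises in each comparison, by 1248 to 134 for DDX5 and DDX17 and by 2174 to 430 for TRA2A and TRA2B.

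Median exon length differed between falling and rising exons after FUS depletion, though their quartiles overlapped (86 to 164 nt and 71.75 to 152.25 nt). Falling exons had a median length of 128 nt and rising exons of 104 nt, a difference of 24 nt (95% bootstrap interval 11 to 36.5). The falling exons lay at percentile 99.9 and the rising exons at percentile 0.245 of 10000 random lists of exons from the same table. Both percentiles draw on the falling and rising exons together, so they are not independent. After HNRNPH1 depletion falling exons were shorter, with medians of 108 and 120 nt, but the interval of the difference of -12 nt (-25.5 to 4) included 0. The difference was -23 nt among exons with a PSI difference of at least 0.20 (percentiles 4.1 and 99.7 for falling and rising exons) and -5.5 nt among exons changed in 1 comparison only. The difference was 0.50 nt after DDX5 and DDX17, 1 after HNRNPC, -3 after HNRNPK and -1 after TRA2A and TRA2B depletion, each with an interval that included 0. GC content was not analysed here.

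HNRNPH1 and HNRNPK shared the most exons for the size of their lists. They had 117 skipped exons in common, of which 116 moved the same way, 55 lower and 61 higher. Both lowered PICALM exon 14 (to 0.277 and 0.232 from 0.474), CENPE exon 17 (to 0.50 and 0.419 from 0.815) and EIF4A2 exon 11 (to 0.135 and 0.196 from 0.334), and both raised IRF7 exon 6, NUMB exon 9 (to 0.905 and 0.987 from 0.688), TJP1 exon 24 (to 0.352 and 0.391 from 0.162) and ATRIP exon 8 (to 0.978 and 0.962 from 0.744). ATRIP exon 8 is not particular to this pair. Against the same siGL2 library it also rose after FUS, HNRNPC, and TRA2A and TRA2B depletion (PSI differences of 0.256, 0.198 and 0.256). EIF4A2 exon 11 and TJP1 exon 24 are not particular to the pair either. Against separate controls, EIF4A2 exon 11 fell and TJP1 exon 24 rose after DDX5 and DDX17 depletion (PSI differences of -0.222 and 0.268). The EIF4A2 call was lost without control replicate 1 (-0.209) or 2 (-0.220), and the TJP1 call without control replicate 2 (0.242). HNRNPH1 and HNRNPK also shared donor sites in 54 exons and acceptor sites in 22, each with the same direction. Independent lists of these sizes among the 20835 events in all would share 9.02 exons. Unchanged libraries simulated against 1 shared control shared 2.26, all in the same direction, so part of the excess in each pair of single-library comparisons may come from the shared siGL2 library. The simulation gave each library the same normal noise and held neither the depth of each exon nor a departure of that library from other control cells. The other pairs of single-library comparisons shared 59 to 213 exons against 8.72 to 78.6 in independent lists and 2.19 to 8.83 in the simulation, with 68.2% to 88.5% in the same direction, against 51.0% to 58.8% from the direction balance of the lists. The background counts all events of the authors' analysis, changed or not, and treats each as equally able to pass the thresholds. Where some events can hardly pass, the numbers for independent lists are too low, here and for DDX5 and DDX17 below. By how much cannot be said.

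The DDX5 and DDX17 comparison had its own controls. It shared 66 skipped exons with HNRNPH1 (22.4 in independent lists; 81.8% in the same direction, exact 95% interval 70.4 to 90.2), 87 with HNRNPC (41.7; 72.4%, 61.8 to 81.5), 61 with FUS (35.7; 63.9%, 50.6 to 75.8), 71 with HNRNPK (36.9; 56.3%, 44 to 68.1) and 182 with TRA2A and TRA2B (155; 70.9%, 63.7 to 77.4). The direction balance of the lists alone would give 58.3% for HNRNPH1, 56.7% for HNRNPC, 60.6% for FUS, 55.1% for HNRNPK and 77.0% for TRA2A and TRA2B. The intervals for FUS, HNRNPK and TRA2A and TRA2B included that balance. Exons lower in both numbered 47 for HNRNPH1 (12.2 in independent lists), 54 for HNRNPC (22), 31 for FUS (20.3), 33 for HNRNPK (18.7) and 112 for TRA2A and TRA2B (117). Exons higher in both numbered 7 (0.862), 9 (1.69), 8 (1.27), 7 (1.56) and 17 (2.48), in the same order. Of all changed skipped exons, 3938 changed in 1 comparison, 62 in 4 or more and 1 in all 6, exon 15 of TBC1D23, a Golgi-associated gene. This exon (chromosome 3, 100030677 to 100030721) fell from 0.438 ± 0.11 to 0.150 ± 0.013 after DDX5 and DDX17 depletion (SD, n = 3; limma adjusted p = 0.021), a call lost without control replicate 1 (difference -0.235) or 3 (-0.285). From 0.583 in the single control it fell to 0.365 after FUS, 0.341 after HNRNPH1, 0.285 after HNRNPK and 0.377 after TRA2A and TRA2B depletion, and it rose to 0.755 after HNRNPC depletion. Some exons moved in opposite directions in different depletions. Exon 4 of HIRIP3 fell from 0.595 ± 0.11 to 0.167 ± 0.032 after DDX5 and DDX17 depletion and from 0.561 to 0.167 after HNRNPC and 0.212 after TRA2A and TRA2B depletion, but rose to 0.962 after HNRNPK depletion. Exon 4 of NHLRC3 fell from 0.503 ± 0.026 to 0.0365 ± 0.041 after DDX5 and DDX17 depletion, and rose from 0.442 to 0.904 after FUS, 0.660 after HNRNPH1 and 0.879 after TRA2A and TRA2B depletion. Exon 12 of MLPH, a melanosome transport gene, fell from 0.880 ± 0.033 to 0.476 ± 0.065 after DDX5 and DDX17 depletion, but rose from 0.806 to 0.922 after TRA2A and TRA2B depletion.

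**Figure D4:**
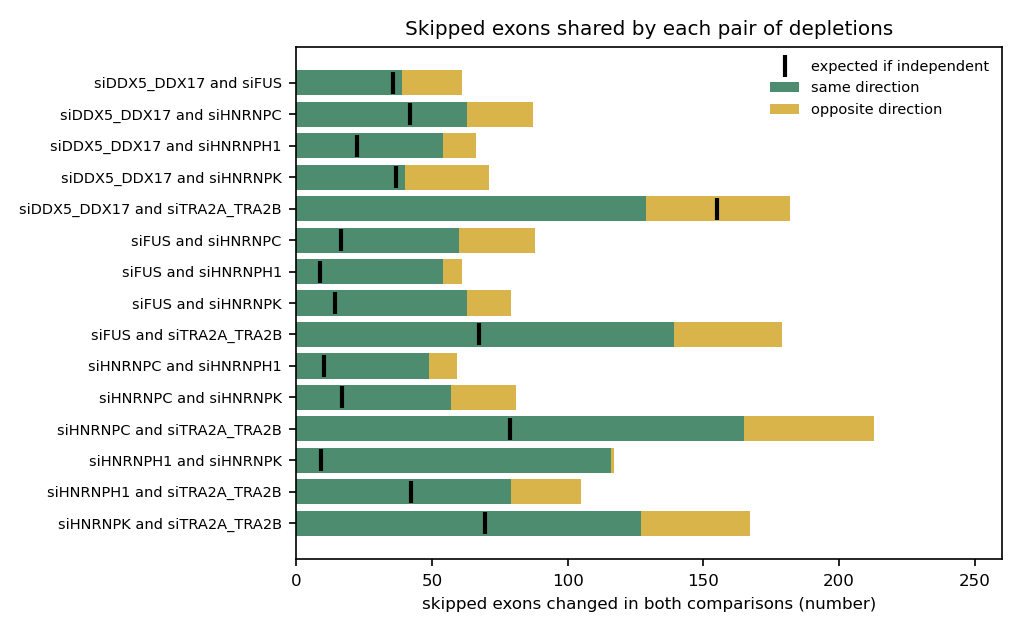
Number of skipped exons changed in both comparisons of each pair, split into the same direction (green) and opposite directions (yellow), with the number expected of independent lists as a black line. HNRNPH1 and HNRNPK share 117 exons against 9.02, of which 116 have the same direction.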

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

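The 0.001 and 0.05 added to PSI, untransformed PSI, kept missing values, 1 event per set of coordinates, a corrected p of 0.01, the control PSI range of 0.3 to 0.7, the authors' calls in overlaps, and the extra settings for other event types and for the share after DDX5 and DDX17 depletion were chosen after seeing the data. Of 124 values of 27 results under alternatives, 93 stayed within their limits and 31 moved; the cause of a move was not tested. With the authors' p-values, changed skipped exons after DDX5 and DDX17 depletion were 2553 (1382 in limma) and other events 1921 (824). Without 1 library the count of skipped exons was 1101 to 1523, and in the other limma or quasibinomial settings 946 to 1581. The share with lower inclusion (90.3%) was 76.4% at a control PSI of 0.3 to 0.7, 91.9% with the quasibinomial model, 92.7% with 0.001 added, and 90.7% to 93.0% without 1 library. For FUS, HNRNPC, HNRNPH1 and HNRNPK, a PSI difference of 0.20 left 243, 298, 135 and 250 exons and a corrected p of 0.01 left 329, 395, 174 and 318. For TRA2A and TRA2B, 0.20 left 1500. Other events of the single-library tables went from 5409 to 2786 at 0.20 and 3148 at p 0.01. At a control PSI of 0.3 to 0.7 the share lower was 45.2% after FUS, 50% after HNRNPC, 43.8% after HNRNPH1, 40.8% after HNRNPK and 57.0% after TRA2A and TRA2B depletion. It crossed 50% for FUS, HNRNPH1 and HNRNPK. At 0.20 it was 53.0% after HNRNPC, 51.6% after HNRNPK and 85.5% after TRA2A and TRA2B, and 84.9% for the last with runs of exons added. The difference in exon length after HNRNPH1 depletion (-12 nt) was -23 at 0.20, -6 with exons of 30 to 300 nt and -5.5 with exons in 1 comparison only. It changed sign for HNRNPK (-3 to 5 nt with exons of 30 to 300 nt, 3 with exons in 1 comparison only) and for TRA2A and TRA2B (-1 to 4 with exons in 1 comparison only), both with intervals that include 0. Of 74 gene list counts, 20 stayed within 1.5 times at 0.20 and 54 went down.

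Of 88 named skipped exons after DDX5 and DDX17 depletion, 50 were past the thresholds in each setting and 38 were lost in 1 or more: 10 to 25 without 1 library, 22 with 0.001 added, 9 with the quasibinomial model, 3 at 0.20, 2 with untransformed PSI and 2 with missing values kept. The runs in TRA2A and TRA2B passed with the authors' p-values, that in TRA2A also with 0.05 added, and that in TRA2B also without depleted replicate 2 (-0.203) or 3 (-0.104).

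No pairing by replicate number was seen: same-number correlations of the deviations were 0.0037, -0.0098 and 0.0080. This cannot exclude pairing, since 46.8%, 64.9% and 55.5% of the PSI values of listed skipped exons were at 1 in the 3 control libraries. The labels do not say whether the numbers pair the libraries. With the replicate block, 1259 skipped exons and 709 other events changed, and 92.6% of the skipped exons were lower. The block lost 19 named skipped exons, among them TBC1D23 exon 15 (-0.289), and also the run of exons 2 and 3 of HNRNPC (-0.279).

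Not run, for lack of read counts, were read minimums, halved inclusion reads, pseudocounts in reads, library scaling, count-based tests, the recomputed Fisher test and the beta-binomial test. A PSI difference of 0.05 was not run for the single libraries, whose tables start at 0.10. Events for DDX5 and DDX17 were also listed only from 0.10. The run at 0.05 there (1425 skipped exons) could thus add no event below that listing and says little about the threshold.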

Other observations

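All tests in this part were chosen after the result was seen. Of the skipped exons, 62 changed in 4 or more comparisons. Exon 2 of KLHL20 was higher in 4, reaching 0.440 after HNRNPK and 0.449 after TRA2A and TRA2B depletion from 0.203. Exon 5 of CCDC125 was lower in 4, reaching 0.266 after FUS, 0.308 after HNRNPC and 0.0606 after TRA2A and TRA2B depletion from 0.556, and falling from 0.644 ± 0.15 to 0.0939 ± 0.066 after DDX5 and DDX17 depletion (n = 3). Exon 11 of NUMB, a regulator of Notch, was lower after FUS (0.625), HNRNPC (0.444), HNRNPK (0.577) and TRA2A and TRA2B depletion (0.642) than in the control (0.865). Exon 30 of the motor gene MYO5A rose from 0.456 to 0.825 after FUS, 0.747 after HNRNPC and 0.672 after HNRNPK, but fell to 0.216 after TRA2A and TRA2B depletion. Exon 13 of OS9, a gene of endoplasmic reticulum degradation, rose from 0.463 to 0.633 after HNRNPH1 and 0.772 after HNRNPK but fell to 0.235 after HNRNPC depletion.

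Other event types held large single switches. After TRA2A and TRA2B depletion a donor of exon 3 of FAM35A (now SHLD2), a gene of break repair, fell from 0.937 to 0.0721, and an acceptor of exon 5 of ETAA1, an activator of ATR, from 0.947 to 0.0909. After HNRNPC depletion the listed form of the mutually exclusive exons 2 and 3 of the chaperonin gene CCT3 rose from 0.423 to 1. After FUS depletion a run of exons 12 and 13 of the transcription factor NFIB fell from 0.969 to 0.333. For each run of exons, the lengths of the introns between its skipped exons were averaged. Introns flanking the run were not measured. The median of these averages was 795 nt (95% bootstrap interval 720 to 906) for runs that fell after DDX5 and DDX17 depletion. For runs that fell after TRA2A and TRA2B depletion, this median was 2271.5 nt (2102 to 2430). For falling runs it was 777.5 nt (461 to 1350) after HNRNPH1, 1645 (1254 to 2016.5) after FUS, 1576 (1073 to 2016.5) after HNRNPC and 1770.5 (1163 to 2107) after HNRNPK depletion. For runs that rose it was 2500.8 nt (1673.5 to 3814.6) after DDX5 and DDX17, 1812 (889 to 3214) after HNRNPH1, 2348 (1293 to 3836) after FUS, 2482.5 (1490.5 to 4817) after HNRNPC, 2256 (1217 to 4542) after HNRNPK and 1748.5 (1221 to 2122) after TRA2A and TRA2B depletion. The intervals of falling and rising runs overlap in each comparison but that of DDX5 and DDX17, and the differences were not tested.

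Falling exons outnumbered rising ones after DDX5 and DDX17 depletion. A control PSI near 1 leaves room only for falls, but 76.4% also fell where the control PSI was 0.3 to 0.7 (66.2 to 84.8), which argues against it as the whole cause. Fewer reads in the depleted libraries stay open: a PSI was missing for 3.67% of listed exons in a depleted library on average and 0.601% in a control, and without read counts depth cannot be told apart from lower expression of these genes. Of the 10 splits of the 6 libraries, the real one gave 1382 skipped exons, 525 runs, 115 acceptor, 179 donor and 5 mutually exclusive events, 1 split as large in each type, and the highest other gave 0. The splits are too few for a share under 0.05, and the events had been selected by the authors on the real split.

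HNRNPH1 and HNRNPK depletion shared 117 skipped exons, 116 in the same direction. A chance value of the shared siGL2 library would place that library away from the 3 other siGL2 libraries by about the size of the change. The median distance was 0.126 of it (-0.0204 to 0.255), but only for the 38 of 116 exons that also changed in the authors' table for DDX5 and DDX17, the only ones with values in the other controls. These respond in a second experiment and may favour real changes, so the explanation stays open for HNRNPH1 and HNRNPK. For FUS and HNRNPH1 it was 0.576 (16 of 54 exons, 0.281 to 0.902) and for FUS and HNRNPK 0.493 (19 of 63, 0.0117 to 0.773). Both intervals include 0.5, the cut chosen between this explanation and its absence. In the other pairs the median lay from -0.223 (FUS and HNRNPC) to 0.211 (HNRNPK with TRA2A and TRA2B). Intervals lay wholly below 0.5 for FUS with HNRNPC and with TRA2A and TRA2B, and for HNRNPC with HNRNPH1 and with TRA2A and TRA2B. The rest of these pairs reached beyond 0.5. Each value covers only exons also listed for DDX5 and DDX17, so the explanation stays open for these pairs too. If both libraries came from cells with the same depletion, their falling exons would lie alike, but 26.5% (20.6 to 33.1) of those after HNRNPH1 and 15.3% (11.5 to 19.8) of those after HNRNPK depletion were on chromosomes 16, 17, 19 and 22. A partial mix of the samples stays open, and that both proteins act on these exons may be a further explanation, which was not tested.

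Exons falling after DDX5 and DDX17 depletion lay more often on chromosomes 16, 17, 19 and 22 (25.6%, 23.2 to 28.2) than those falling after TRA2A and TRA2B depletion (10.4%, 9.14 to 11.8). If the experiments had measured exons of different chromosomes, rising exons would differ the same way, but their difference was -13.5 percentage points (11.2% against 24.7%). With 1 exon per gene the difference among falling exons was 14.7 points against 15.2, so a few genes with many exons are not the cause. The share of falling exons on these chromosomes was 26.5% (20.6 to 33.1) after HNRNPH1, 17.6% after FUS, 15.3% after HNRNPK and 12.8% after HNRNPC depletion. Among rising exons it was 11.2% after HNRNPH1, 19.3% after FUS, 18.1% after HNRNPK and 15.6% after HNRNPC depletion. The values after HNRNPH1 were thus close to those after DDX5 and DDX17. A candidate explanation is that the factors act on exons in different gene surroundings, which was not tested. GC content was not analysed here.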
